A study of Mus musculus with 6 samples.

How the data were processed

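RNA was extracted from mesoderm explants of mouse embryos with a kit for small samples, and polyadenylated RNA was made into libraries with a low-input template-switching kit that does not keep the strand. Explants were freed of other tissue after trypsin and pancreatin, left to attach to fibronectin for 3 to 4 h, and treated for 16 h. The growth protocol gives 27 h of culture and the series description 24 h, and the labels give the genotype as wild type where the series description names a WNT reporter strain. Whether controls received the vehicle is not stated. The labels name 6 samples in 3 groups of 2: control, PD and YZ9.

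Per the labels, the authors used CASAVA 1.8.2, STAR 2.7.9a and DESeq2 1.40.1 with the build GRCm38. The counting step, the annotation release and any filter are not given in the sources used here. Of the deposited tables, 1 compares PD with control and 1 compares YZ9 with control, each with 46078 genes. Per the file headers, each table holds a whole-number count per gene and library, and the values are counts. The deposited normalized columns hold a signal in which each count is divided by 1 size factor per library, computed within the 4 libraries of that table. The deposited log2 fold change and its standard error are on the log2 scale, and the deposited p-value and adjusted p-value columns are those of the authors' DESeq2 test. The control counts are identical in both tables, so the counts were joined into 1 table of 6 libraries. The authors' fold changes were not used here except for their number of genes past an adjusted p of 0.05.

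Genes were filtered with filterByExpr of edgeR (minimum count 10, minimum total 15), which left 15568 genes, and scaled by TMM. Groups were compared in R 4.3.3 with edgeR 4.0.16 by quasi-likelihood (glmQLFit, glmQLFTest), with all 6 libraries in 1 fit, 2-sided, and Benjamini-Hochberg adjustment with a threshold of 0.05. The common dispersion was 0.101. Standard errors are the absolute log2 fold change over the square root of F. CPM were computed from TMM-scaled library sizes, and SD are between the 2 libraries of a group. With 3 counts or fewer in a group, the fold is given against a floor of 3 counts over the group (0 counts) or as a ratio with an exact 95% binomial interval (1 to 3 counts). Total counts per library were 21253194 to 27810161. Chi-square statistics per gene between the 2 libraries of a group were 54.7 in controls, 96.0 in PD and 62.2 in YZ9, where sampling alone gives about 1, so counting error is a small part of the spread, and the spread between libraries sets the precision.

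Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with adjustment over the 93 tests of 31 lists in 3 comparisons. Lists needed 4 measured members. They covered ERK feedback targets, glycolysis, hexosamine, pentose phosphate, citric acid cycle, oxidative phosphorylation, cholesterol synthesis, hypoxia, ATF4, unfolded protein, p53, cell cycle, WNT, FGF, Notch and BMP or TGF-beta genes. They further covered primitive streak, paraxial, lateral, cardiac, blood and endothelial, migration, Hox, epiblast, ectoderm, definitive endoderm, visceral endoderm and trophoblast genes, and immediate early, mitochondrially encoded and ribosomal genes. The lists, the tests, the grouping and the first set of alternative settings were chosen before the data were examined.

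Named genes followed a rule of the same date. The rule took up to 8 genes with the largest rise and up to 8 with the largest fall among named genes past the threshold. These needed a mean normalized count of at least 50 in the higher group and both treated libraries beyond both controls. Of each list it took up to 4 members past the threshold or, where none passed, the member with the smallest p. It always took Dusp6, Spry4, Etv4, Etv5, Pfkfb3, Slc2a1, Hk2, Ldha, T, Tbx6 and Mesp1. Other genes named as examples, and all genes named first in the comparison of PD with YZ9, were chosen after their values were seen. Positions come from GENCODE M21.

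The settings varied were DESeq2 size factors, no filter, a mean count of at least 50, DESeq2 1.42.0 (run without the filter), limma-trend (prior count 3), the 4 libraries of a comparison alone, the replicate number as a block, a log2 fold of at least 1, leaving out each library, and for lists an estimated correlation, fry and camera on ranks. Added after the data were seen were edgeR's newer quasi-likelihood fit, DESeq2 on the filtered genes, sex as a covariate, and the male libraries alone. Alternatives for pseudocounts and recovered reads did not apply to counts. The pipeline was tested on simulated data at the depth and spread of these libraries, with 67, 67 and 66 genes of 15568 changed by 2-fold, 4-fold and 8-fold in a simulated PD group. edgeR recovered 4.48%, 74.6% and 84.8% of them with 7 false calls (5.88% of calls), and limma-trend 4.48%, 71.6% and 84.8% with 7. DESeq2 recovered 22.4%, 83.6% and 92.4% with 43 false calls (22.8%). In the simulated unchanged YZ9 group edgeR made 1 false call and DESeq2 21. A list of 30 further genes was raised 2-fold in the same simulated group, and calls of these genes are among the calls behind the false shares. That list gave a camera adjusted p of 3.78e-28 with the preset and 0.0609 with an estimated correlation, and 0 of 60 unchanged lists passed with either. Genes were simulated independently of each other, so this does not test whether the preset correlation holds in the data.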

Results

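Polyadenylated RNA was sequenced from explants of mouse mesoderm, the germ layer that leaves the primitive streak during gastrulation. The explants were dissected from embryos at the late streak to no bud stage and cultured on fibronectin, a matrix protein on which mesoderm cells spread and migrate. The 6 libraries fell into 3 groups of 2: control explants, explants treated for 16 h with 1 µM of an inhibitor that the labels call PD, and explants treated for 16 h with 10 µM YZ9. YZ9 is known as an inhibitor of PFKFB3, an enzyme that makes an activator of glycolysis. Total counts were 27231057 and 27529450 in the control libraries, 27066702 and 25395141 in the PD libraries, and 21253194 and 27810161 in the YZ9 libraries, and between 20112 and 20933 genes had a count. The 10 most abundant genes took between 4.43% and 6.23% of a library's counts.

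The libraries differed in the sex read from their counts, which the labels do not state. Xist, the RNA that silences an X chromosome in females, had 2119 counts in PD replicate 2 and 3956 in YZ9 replicate 2, and between 0 and 1 in the other libraries. The 4 Y-linked genes summed to 8875 and 9703 counts in the controls, 9736 in PD replicate 1 and 4286 in YZ9 replicate 1, against 3 in PD replicate 2 and 0 in YZ9 replicate 2. Both controls were thus male, and each inhibitor group held 1 male and 1 female library. The labels do not say whether the 2 libraries of a group came from separate embryos or cultures. The differing sex shows that the 2 PD libraries came from different embryos, and so did the 2 YZ9 libraries. For the 2 male controls this stays open, as it does for separate cultures in every group. The p-values measure the spread between these libraries alone. Intervals and floors cover counting error only.

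PD was compared with control to ask how the inhibitor changed the transcriptome of mesoderm explants, in a series about glucose metabolism during gastrulation. Targets and feedback inhibitors of the ERK pathway fell. Spry4, an inhibitor of growth factor receptor signalling, had 630 and 699 counts in the controls and 0 in both PD libraries, at least 423-fold lower against a floor of 3 counts over the PD group (adjusted p = 0.0378). Egr1, an immediate early transcription factor induced by ERK, dropped from 37.7 ± 12.2 to 0.0586 ± 0.0259 CPM, counts scaled to the effective library size (SD, n = 2). The ratio was 639 (95% counting interval 218 to 3102, adjusted p = 0.0417). Spry2, another inhibitor of receptor signalling, fell from 89.4 ± 18.5 to 6.36 ± 2.91 CPM (log2 fold change -3.81, SE 0.36, adjusted p = 0.0417). Spred1, which restrains the RAS to ERK cascade, fell from 51.5 ± 2.20 to 6.86 ± 0.0273 CPM (log2 fold change -2.91, SE 0.21, adjusted p = 0.0378). Ccnd1, the cyclin D1 gene that promotes entry into the cell cycle, fell from 95.5 ± 25.2 to 9.44 ± 0.251 CPM (log2 fold change -3.34, SE 0.26, adjusted p = 0.0378). Of the 31 measured members of the ERK list, 0 rose, 5 fell and 26 did not pass over all genes. When adjusted over the list alone, 19 fell and 0 rose. The list's median log2 fold change was -2.50, the same with its 3 members at 0 counts set to their bounds (camera adjusted p = 1.84e-54, and adjusted p = 0.421 with an estimated correlation). The list passed the preset test in each of the 6 fits that left out 1 library.

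Other ERK targets had large differences that did not pass over all genes. Dusp6, the phosphatase that inactivates ERK, was at 233 ± 9.93 CPM in controls and 2.75 ± 2.30 CPM with PD (n = 2, log2 fold change -6.40, SE 0.73, adjusted p = 0.0655). It became -7.69 without PD replicate 1 (adjusted p = 0.0388) and -5.73 without PD replicate 2 (adjusted p = 0.0451), and Dusp6 passed under 12 of 17 alternatives, with adjusted p from 5.72e-25 to 0.447. Etv5, an ETS factor downstream of FGF signalling, had 401 and 261 counts in controls and 0 in both PD libraries, at least 211-fold lower (adjusted p = 0.0975). Etv4, a related factor, had 172 and 63 counts in controls and 0 in both PD libraries, at least 74.8-fold lower (adjusted p = 0.127). Hmga2, a chromatin protein of embryonic cells, had a log2 fold change of -2.34 (SE 0.39, adjusted p = 0.121). The gene positions in GRCm38 were chromosome 18, 38586247 to 38601415, for Spry4 (ENSMUSG00000024427) and chromosome 18, 34859823 to 34864984, for Egr1 (ENSMUSG00000038418). Spry2 (ENSMUSG00000022114) lies on chromosome 14, 105891947 to 105896819, and Spred1 (ENSMUSG00000027351) on chromosome 2, 117121374 to 117182279. Ccnd1 (ENSMUSG00000070348) lies on chromosome 7, 144929931 to 144939925, and Dusp6 (ENSMUSG00000019960) on chromosome 10, 99263231 to 99267489. Exons of Ccnd1 overlap a gene on the opposite strand, and because the library kit keeps no strand, reads of the overlap cannot be assigned to a strand.

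**Figure D1:**
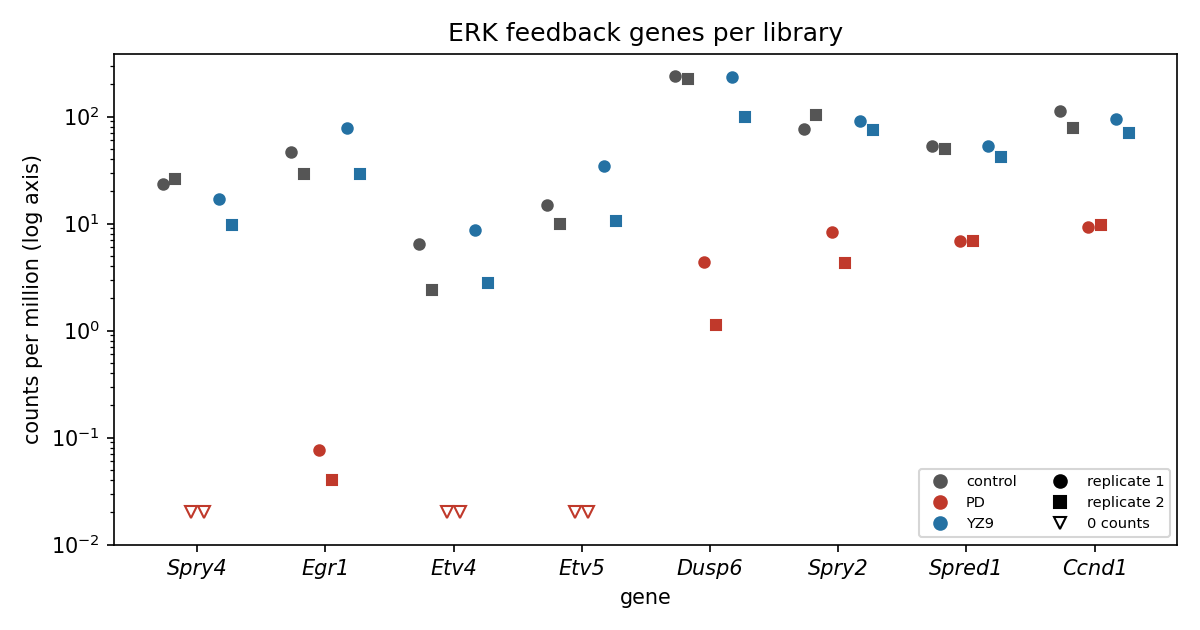
CPM on a log axis for 8 genes of the ERK list, with 1 point per library, coloured by group and shaped by replicate, and open triangles where a library had 0 counts. Spry4, Etv4 and Etv5 had 0 counts in both PD libraries, and Dusp6 was at 2.75 ± 2.30 CPM with PD (SD, n = 2) against 233 ± 9.93 CPM in controls.

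Outside the ERK list, 3 genes rose with PD. Vnn1, a pantetheinase of the vitamin B5 pathway, rose from 43.8 ± 0.587 to 257 ± 59.6 CPM (n = 2, log2 fold change 2.55, SE 0.22, adjusted p = 0.0417). Nkain4, which encodes a protein that interacts with the sodium pump, rose from 28.9 ± 2.86 to 142 ± 0.441 CPM (log2 fold change 2.30, SE 0.22, adjusted p = 0.0417). Wdr72 rose from 0.582 ± 0.0284 to 10.4 ± 0.253 CPM (log2 fold change 4.14, SE 0.44, adjusted p = 0.0466). Ccnd2, the cyclin D2 gene, fell from 520.1 ± 61.1 to 114 ± 17.6 CPM (log2 fold change -2.19, SE 0.23, adjusted p = 0.0466). Tubb1, the beta-tubulin of megakaryocytes and platelets, fell from 19.1 ± 2.48 to 2.52 ± 0.0295 CPM (log2 fold change -2.92, SE 0.30, adjusted p = 0.0463). Kctd12b, Morrbid, Ppp1r14c, Dcaf12l1 and Chn2 also fell, with log2 fold changes of -3.40, -3.48, -3.61, -2.97 and -2.54 (adjusted p = 0.0417, 0.0466, 0.0463, 0.0417 and 0.0417). Chn2 is outside the naming rule and was chosen after its values were seen. Vnn1 lies on chromosome 10, 23894688 to 23905343, Nkain4 on chromosome 2, 180934772 to 180954699, Wdr72 on chromosome 9, 74110356 to 74283308, and Ccnd2 on chromosome 6, 127125162 to 127152193. Tubb1 did not pass with limma-trend (adjusted p = 0.0582) or in the 4 libraries alone (adjusted p = 0.0503), Wdr72 did not with edgeR's newer fit (adjusted p = 0.0522), Ppp1r14c did not in the 4 libraries alone (adjusted p = 0.0506) or with the newer fit (adjusted p = 0.0522), and Chn2 did not in the 4 libraries alone (adjusted p = 0.0538). Nkain4, Ccnd2, Ppp1r14c and Morrbid share exon sequence with genes on the opposite strand.

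In all, edgeR called 3 genes higher and 12 lower with PD among 15568 tested, and 1682 genes had an unadjusted p under 0.05, where chance gives 778.4. The number of calls rested on the model and on single libraries. With the replicate number as a block edgeR called 1 gene. Without control replicate 1 and without control replicate 2 edgeR called 0 genes (1314 and 1117 with an unadjusted p under 0.05), without PD replicate 1 it called 25 and without PD replicate 2 it called 31, each sharing 6 with the 15. Without YZ9 replicate 1 it called 33 and without YZ9 replicate 2 it called 29, all 15 among them. DESeq2 called 629 genes on the filtered genes and 604 without the filter, limma-trend called 20, and the authors' deposited table lists 293 higher and 301 lower genes at an adjusted p under 0.05.

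The glycolysis list did not pass with PD. It had a median log2 fold change of 0.12 over 29 measured genes (camera adjusted p = 0.476), and 0 of its members passed over all genes in edgeR. When adjusted over the list alone, 1 rose and 2 fell. Slc2a3, a glucose transporter of embryonic cells, was at 368 ± 122 CPM in controls and 1539.7 ± 545 CPM with PD (n = 2, log2 fold change 2.06, SE 0.32, adjusted p = 0.106). Slc2a1, the glucose transporter most tissues express, was at 1618 ± 636 and 4703 ± 2238 CPM (log2 fold change 1.54, SE 0.40, adjusted p = 0.228), which became 0.95 without PD replicate 2. Hk2, a hexokinase, had a log2 fold change of -0.85 (SE 0.15, adjusted p = 0.131), and Pgam2, a phosphoglycerate mutase, of -2.16 (SE 0.33, adjusted p = 0.106). Slc2a1, Hk2 and Pgam2 each passed under 3 of 17 alternatives, and Pfkfb3 and Ldha under 0. Pfkfb3 had a log2 fold change of -0.63 (SE 0.60, adjusted p = 0.829), which became 0.0142 without control replicate 1. Ldha, a lactate dehydrogenase subunit, had a log2 fold change of 0.12 (SE 0.33, adjusted p = 0.961), which became -0.56 without PD replicate 2, -0.28 with sex in the model and -0.56 in the male libraries alone.

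Of the 31 gene lists, 3 rose and 9 fell with PD by camera. Cholesterol synthesis rose, with a median log2 fold change of 0.64 over 24 genes (adjusted p = 3.23e-09, and adjusted p = 0.668 with an estimated correlation). Adjusted over the list alone, 9 members rose and 0 fell, although 0 passed over all genes in edgeR. Cyp51, which demethylates lanosterol, was at 179.7 ± 12.7 and 297 ± 4.11 CPM (n = 2, log2 fold change 0.72, SE 0.14, adjusted p = 0.157), and Sqle, the squalene epoxidase, had a log2 fold change of 0.81 (SE 0.21). The primitive streak list fell, with a median of -1.15 over 17 genes and 4 members lower when adjusted over the list alone (adjusted p = 3.43e-07, and adjusted p = 0.486 with an estimated correlation). Among these members, Eomes, a T-box factor of the early streak, had 185 and 145 counts in controls and 0 in both PD libraries, at least 105-fold lower (adjusted p = 0.106). Fgf8, a growth factor of the streak, had 121 and 60 counts in controls and 25 and 9 with PD. T, Tbx6 and Mesp1, markers of the streak and early mesoderm, had too few counts to be tested: T had 0 and 0 in controls, 0 and 8 with PD and 2 and 4 with YZ9, Tbx6 between 0 and 3 per library and Mesp1 between 0 and 7. The cholesterol and streak lists passed the preset test in each fit that left out 1 library.

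The definitive endoderm list rose with PD, with a median log2 fold change of 1.91 over 15 genes, 6 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.85e-04, and adjusted p = 0.748 with an estimated correlation). Its members that moved include general epithelial genes. Cdh1, the E-cadherin gene, had 49 and 101 counts in controls and 2076 and 537 with PD (adjusted p = 0.176), and Cldn6, a tight junction gene, had 7 and 220 in controls and 11667 and 1404 with PD (adjusted p = 0.234). Foxa2, an endoderm transcription factor, was at 0.0753 ± 0.106 and 4.84 ± 2.35 CPM (n = 2, log2 fold change 5.92, SE 1.01, adjusted p = 0.127). That value was 4.96 without control replicate 1 and 5.32 without PD replicate 1, and 9.97 without control replicate 2, which leaves controls at 0 counts and a fitted value that is no bound. PD replicate 1 stood apart in genes of the visceral endoderm, the outer layer of the embryo: 8 abundant genes of that layer, picked after the values were seen and all in the fixed lists, summed to 88.2 CPM there, against 16.5 in PD replicate 2 and 4.65 and 8.69 in controls. The Hox list rose with a median of 1.30 over 18 genes (adjusted p = 0.00461, and adjusted p = 0.798 with an estimated correlation), and it did not pass without control replicate 2 (adjusted p = 0.0719) or with sex in the model (adjusted p = 0.295). Hoxb1 and Hoxb2 rose when adjusted over the list alone. Hoxb1 had 33 and 21 counts in controls and 1625 and 269 with PD.

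Cardiac mesoderm genes fell with PD (median log2 fold change -0.61 over 32 genes, camera adjusted p = 1.85e-04, and adjusted p = 0.812 with an estimated correlation), and did not pass without PD replicate 2 (adjusted p = 0.325) or in the male libraries alone (adjusted p = 0.238). Adjusted over the list alone, Mef2c and Actn2 fell and Wnt2, a WNT ligand gene, rose (log2 fold change 2.04, SE 0.40). Mef2c, a cardiac and vascular transcription factor, was at 192 ± 13.2 and 49.1 ± 25.3 CPM (n = 2, log2 fold change -1.97, SE 0.38, adjusted p = 0.154), which became -2.62 without PD replicate 1. Targets of p53 fell (median -0.32 over 21 genes, adjusted p = 0.00148, and adjusted p = 0.759 with an estimated correlation), with 3 lower when adjusted over the list alone, among them Trp53inp1 at a log2 fold change of -0.80 (SE 0.17). Notch pathway genes fell (median -0.28 over 16 genes, adjusted p = 0.00804, and adjusted p = 0.759 with an estimated correlation). Jag1 and Hes1 fell when adjusted over the list alone, and 0 members rose. The Notch ligand gene Jag1 was at 155 ± 17.4 and 15.7 ± 9.22 CPM (log2 fold change -3.30, SE 0.47, adjusted p = 0.106), and its log2 fold change was -4.07 without PD replicate 1. The Notch list did not pass without control replicate 1 (adjusted p = 0.163) or PD replicate 2 (adjusted p = 0.0857), nor with camera on ranks (adjusted p = 0.0836) or in the male libraries alone (adjusted p = 0.144). The blood and endothelial list fell (median -0.26 over 35 genes, adjusted p = 0.0194, and adjusted p = 0.486 with an estimated correlation), with 0 members past the threshold over the list alone, and did not pass without control replicate 2 (adjusted p = 0.103) or PD replicate 1 (adjusted p = 0.0647).

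Lists that can mark RNA quality or handling moved with PD as well. The mitochondrially encoded genes fell (median log2 fold change -0.34 over 9 genes, camera adjusted p = 0.0127, and adjusted p = 0.798 with an estimated correlation), and took 1.08% and 1.13% of counts in controls, 0.951% and 0.806% with PD and 0.943% and 0.922% with YZ9. The call ended without control replicate 2 (adjusted p = 0.054) and PD replicate 2 (adjusted p = 0.251), with sex in the model (adjusted p = 0.114) and in the male libraries alone (adjusted p = 0.224). No mitochondrially encoded member passed over the list alone. Ribosomal protein genes fell (median -0.16 over 42 genes, adjusted p = 0.0128, and adjusted p = 0.896 with an estimated correlation), with 0 members past the threshold over the list alone, a call that ended without control replicate 2 (adjusted p = 0.304) and PD replicate 1 (adjusted p = 0.254). The immediate early list, which tissue dissociation induces, fell (median -0.09 over 25 genes, adjusted p = 0.0464, and adjusted p = 0.896 with an estimated correlation). Of its members Egr1 alone passed over all genes, and Egr1, Btg2 and Myc fell when adjusted over the list alone. Egr1 and Myc are also members of the ERK list, so the fall of the immediate early list cannot be read as a sign of handling. For this list the call ended without control replicate 1 (adjusted p = 0.286) and PD replicate 2 (adjusted p = 0.575), with camera on ranks (adjusted p = 0.610), with sex in the model (adjusted p = 0.701) and in the male libraries alone (adjusted p = 0.744).

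YZ9 was compared with control to ask how this inhibitor, known to act on PFKFB3, changed mesoderm explants. A single gene passed over all genes. Tubb1 (ENSMUSG00000016255, chromosome 2, 174450695 to 174457882), the beta-tubulin of megakaryocytes and platelets, fell from 19.1 ± 2.48 to 0.286 ± 0.0246 CPM (n = 2, log2 fold change -6.03, SE 0.36, adjusted p = 0.0193). In edgeR 0 genes rose. At an unadjusted p under 0.05 there were 1755 genes, DESeq2 called 519 on the filtered genes and 509 without the filter, limma-trend called 1, and the authors' deposited table lists 180 higher and 406 lower genes. Tubb1 did not pass without control replicate 1 (adjusted p = 0.306), control replicate 2 (adjusted p = 0.445), YZ9 replicate 1 (adjusted p = 0.0963) or YZ9 replicate 2 (adjusted p = 0.217), and passed under the other 13 of 17 alternatives, with adjusted p from 9.57e-30 to 0.445 over all of them. Without PD replicate 1 edgeR called 8 genes and without PD replicate 2 it called 9.

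The WNT target list rose with YZ9. Its median log2 fold change was 0.68 over 17 genes (camera adjusted p = 2.26e-05, and adjusted p = 0.421 with an estimated correlation), and 4 members rose and 0 fell when adjusted over the list alone. Sp5, a transcription factor induced by WNT, was at 0.300 ± 0.0540 and 3.19 ± 0.879 CPM (n = 2, log2 fold change 3.38, SE 0.63, adjusted p = 0.181). Axin2, a feedback inhibitor of WNT signalling, was at 1.97 ± 0.298 and 7.31 ± 1.18 CPM (log2 fold change 1.89, SE 0.35, adjusted p = 0.181). Tbx3, a T-box factor, had a log2 fold change of 3.34 (SE 0.62, adjusted p = 0.181, and 4.14 without control replicate 1), and Nkd1, another feedback inhibitor, of 1.25 (SE 0.32, adjusted p = 0.257). The WNT ligand gene Wnt6, a member of the surface ectoderm list, was at 0.263 ± 0.000812 and 13.6 ± 4.45 CPM (log2 fold change 5.67, SE 0.53, adjusted p = 0.114). The WNT list passed in each fit that left out 1 library, with sex in the model and in the male libraries alone.

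The glycolysis list did not pass with YZ9 either. It had a median log2 fold change of -0.08, a mean of 0.11 and an upward test (camera adjusted p = 0.443), and 2 of its 29 members rose when adjusted over the list alone. Slc2a3, the embryonic glucose transporter (chromosome 6, 122727809 to 122801640), was at 368 ± 122 CPM in controls and 1558 ± 218 CPM with YZ9 (n = 2, log2 fold change 2.08, SE 0.32, adjusted p = 0.134). Slc16a1, a lactate transporter, had a log2 fold change of 0.95 (SE 0.18, adjusted p = 0.199). Slc2a1 (chromosome 4, 119108711 to 119137983) was at 0.85 (SE 0.39, adjusted p = 0.472), Hk2 at -0.43 (SE 0.15, adjusted p = 0.377) and Ldha at -0.11 (SE 0.33, adjusted p = 0.922). Slc2a3 passed under 5 of 17 alternatives, Slc2a1 under 1, and Hk2 and Ldha under 0. The log2 fold change of Pfkfb3, the gene of the enzyme that YZ9 targets, was 0.23 (SE 0.59, adjusted p = 0.910). It became 0.87 without control replicate 1, -0.22 without control replicate 2, -0.79 without YZ9 replicate 1 and 0.84 without YZ9 replicate 2.

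The ERK list did not pass with YZ9 (median log2 fold change -0.14 over 31 genes, camera adjusted p = 0.305), and 0 of its members passed in edgeR, over all genes or over the list alone. Dusp6 was at 167 ± 94.7 CPM with YZ9 (n = 2, log2 fold change -0.48, SE 0.56, adjusted p = 0.773), a value that became -1.21 without YZ9 replicate 1, 0.0186 without YZ9 replicate 2, 0.14 with sex in the model and 0.0188 in the male libraries alone. Spry4 was at 13.3 ± 5.15 CPM (log2 fold change -0.91, SE 0.35, adjusted p = 0.422). Etv4 and Etv5 had log2 fold changes of 0.37 (SE 0.73) and 0.85 (SE 0.59), with adjusted p of 0.874 and 0.628. Without YZ9 replicate 1 these became -0.64 and -0.23, and without YZ9 replicate 2 they became 0.99 and 1.47. Etv4 became 1.26 without control replicate 1 and -0.18 without control replicate 2.

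Of the 31 lists, 6 rose and 4 fell with YZ9. The definitive endoderm list rose (median log2 fold change 2.03 over 15 genes, camera adjusted p = 7.71e-07, and adjusted p = 0.619 with an estimated correlation), with Cdh1, Epcam and Foxa2 higher when adjusted over the list alone. Cdh1 was at 2.82 ± 1.39 and 71.6 ± 57.9 CPM (n = 2, log2 fold change 4.66, SE 0.92, adjusted p = 0.206), which became 5.28 without control replicate 2, 3.45 without YZ9 replicate 1 and 5.33 without YZ9 replicate 2. The 8 visceral endoderm genes summed to 3.99 and 5.87 CPM in the YZ9 libraries. The Hox list rose (median 1.5 over 18 genes, adjusted p = 1.11e-04, and adjusted p = 0.759 with an estimated correlation), as did cholesterol synthesis (median 0.43 over 24 genes, adjusted p = 7.83e-04, and adjusted p = 0.798 with an estimated correlation). Of the Hox and cholesterol lists 0 members passed over the list alone. Without YZ9 replicate 2 neither passed (adjusted p = 0.103 for Hox and 0.1 for cholesterol synthesis), and cholesterol synthesis did not pass with sex in the model (adjusted p = 0.0794) or in the male libraries alone (adjusted p = 0.111). Targets of p53 fell (median -0.32 over 21 genes, adjusted p = 1.83e-04, and adjusted p = 0.668 with an estimated correlation), a call that ended without YZ9 replicate 2 (adjusted p = 0.0525) and in the male libraries alone (adjusted p = 0.0861). Of these, 5 fell when adjusted over the list alone. Fas, a death receptor gene, was at 52.1 ± 6.19 and 23.2 ± 2.86 CPM (log2 fold change -1.16, SE 0.20, adjusted p = 0.172), and Cdkn1a, a cell cycle inhibitor gene, had a log2 fold change of -0.94 (SE 0.22, adjusted p = 0.228).

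The blood and endothelial list fell with YZ9 (median log2 fold change -0.49 over 35 genes, camera adjusted p = 0.0176, and adjusted p = 0.486 with an estimated correlation), and its members split: 3 rose and 6 fell when adjusted over the list alone. Lyl1, a blood transcription factor, was at 11.9 ± 0.621 and 3.87 ± 0.0191 CPM (n = 2, log2 fold change -1.62, SE 0.27, adjusted p = 0.171), and Hbb-y, an embryonic globin, at 447 ± 306 and 7.28 ± 8.59 CPM (adjusted p = 0.241). Kdr, the VEGF receptor of endothelium, had a log2 fold change of 0.72 (SE 0.18, adjusted p = 0.255), and Cldn5, an endothelial junction gene, of 2.10 (SE 0.39, adjusted p = 0.181). The list did not pass without YZ9 replicate 1 (adjusted p = 0.060). The neural and surface ectoderm list passed upward (median 0.12 over 15 genes, adjusted p = 0.0450, and adjusted p = 0.655 with an estimated correlation), with Wnt6 as the 1 member that rose when adjusted over the list alone. The epiblast list passed upward as well (median 0.15 over 11 genes, adjusted p = 0.0465, and adjusted p = 0.655 with an estimated correlation). Its 1 member that rose when adjusted over the list alone was Utf1, a chromatin protein of pluripotent cells, which had 0 counts in both controls and 41 and 64 with YZ9, at least 35.9-fold higher against a floor of 3 counts over the controls (adjusted p = 0.129). The ectoderm call ended without control replicate 2 (adjusted p = 0.211), PD replicate 2 (adjusted p = 0.0838) and YZ9 replicate 2 (adjusted p = 0.111), with camera on ranks (adjusted p = 0.517), with sex in the model (adjusted p = 0.0794) and in the male libraries alone (adjusted p = 0.340). The epiblast call ended without control replicate 1 (adjusted p = 0.109), control replicate 2 (adjusted p = 0.0988), PD replicate 1 (adjusted p = 0.0662), PD replicate 2 (adjusted p = 0.119) and YZ9 replicate 2 (adjusted p = 0.251). It also ended with camera on ranks (adjusted p = 0.443), with sex in the model (adjusted p = 0.194) and in the male libraries alone (adjusted p = 0.525).

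Genes of the unfolded protein response fell with YZ9 (median log2 fold change -0.29 over 22 genes, camera adjusted p = 0.0334, and adjusted p = 0.838 with an estimated correlation). None of its members passed over the list alone. Dnajb9, a chaperone of the endoplasmic reticulum, had a log2 fold change of -0.69 (SE 0.16, adjusted p = 0.241). This call ended without control replicate 1 (adjusted p = 0.064), control replicate 2 (adjusted p = 0.0739), PD replicate 1 (adjusted p = 0.0527), PD replicate 2 (adjusted p = 0.0624) and YZ9 replicate 1 (adjusted p = 0.251). The mitochondrially encoded genes fell as well (median -0.26 over 9 genes, adjusted p = 0.0334, and adjusted p = 0.831 with an estimated correlation). None of their members passed over the list alone. Leaving out any 1 of the 6 libraries ended the mitochondrial call, with adjusted p from 0.0505 to 0.0935, as did sex in the model (adjusted p = 0.192) and the male libraries alone (adjusted p = 0.0861).

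**Figure D2:**
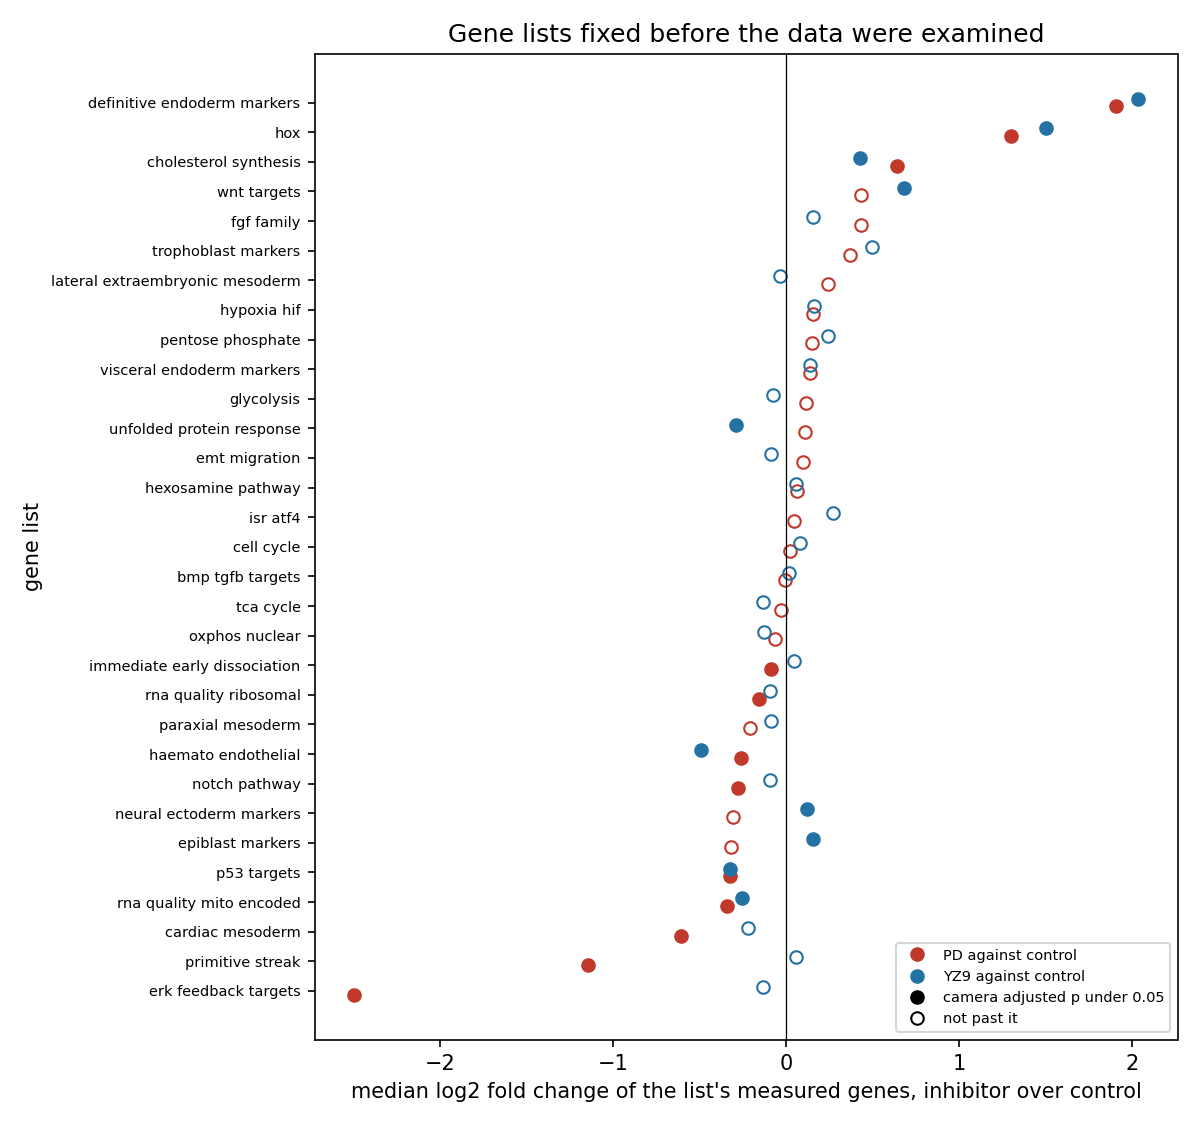
Median log2 fold change of the measured genes of each of the 31 lists (horizontal axis), PD over control and YZ9 over control, with filled points where the camera adjusted p was under 0.05. The ERK list was at -2.50 with PD and -0.14 with YZ9, and the definitive endoderm list at 1.91 and 2.03.

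PD was compared with YZ9 to test the difference between the inhibitors itself. Spry4 was at least 217-fold lower with PD than with YZ9 (0 and 0 counts against 378 and 286, adjusted p = 0.0276). Spred1 was lower by a log2 fold change of -2.79 (SE 0.21, adjusted p = 0.0276), Ccnd1 by -3.12 (SE 0.26, adjusted p = 0.0276) and Spry2 by -3.70 (SE 0.36, adjusted p = 0.0421). Egr1 had 2 and 1 counts with PD against 1766 and 861 with YZ9, a ratio of 857 (95% counting interval 293 to 4157, adjusted p = 0.0276). Id1, a target of BMP signalling that blocks differentiation, was at 12.7 ± 5.01 CPM with PD and 89.7 ± 15.9 CPM with YZ9 (n = 2, log2 fold change -2.82, SE 0.31, adjusted p = 0.0488). Higher with PD than with YZ9 were Vnn1 (log2 fold change 2.15, SE 0.22, adjusted p = 0.0439), Nkain4 (2.37, SE 0.22, adjusted p = 0.0416) and Tubb1 (3.11, SE 0.34, adjusted p = 0.0488). Serpinb6b, Epha3, Nrk and Ripply1, chosen after their values were seen, were also higher with PD, with log2 fold changes of 3.46 (SE 0.28), 3.63 (SE 0.37), 2.57 (SE 0.24) and 2.72 (SE 0.21). Id1 and Tubb1 did not pass with DESeq2 size factors (adjusted p = 0.0519 for each). Tubb1 also did not with limma-trend (adjusted p = 0.0574), edgeR's newer fit (adjusted p = 0.102) or in the male libraries alone. Over all alternatives, Tubb1 passed under 5 of 17 and Id1 under 10 of 17. Of the 15 genes that PD changed against control, 8 also differed from YZ9 in the same direction, and Tubb1 in the opposite one.

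The ERK list was lower with PD than with YZ9 (median log2 fold change -2.17, camera adjusted p = 3.35e-46, and adjusted p = 0.421 with an estimated correlation), with 5 members lower over all genes and 17 over the list alone. The WNT target list was lower with PD (median -1.07 over 17 genes, adjusted p = 6.83e-08, and adjusted p = 0.421 with an estimated correlation), with 7 members lower when adjusted over the list alone, among them Ccnd2, Fgf8, Sp5 and Tbx3. Against control the WNT list did not pass with PD, where its median was 0.43, its mean -0.01 and the test downward (adjusted p = 0.475). The primitive streak list was lower with PD (median -1.96 over 17 genes, adjusted p = 3.64e-08, and adjusted p = 0.421 with an estimated correlation), with 8 members lower when adjusted over the list alone, and the epiblast list too, with 4 lower (median -0.80 over 11 genes, adjusted p = 8.17e-05, and adjusted p = 0.421 with an estimated correlation). Lin28a, a regulator of microRNA processing in embryonic cells, was at 186 ± 47.2 CPM with PD and 435 ± 39.9 CPM with YZ9 (n = 2, log2 fold change -1.23, SE 0.20, adjusted p = 0.108). The ERK, WNT, streak and epiblast calls held in each fit that left out 1 library.

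The unfolded protein response list was higher with PD than with YZ9 (median log2 fold change 0.35, camera adjusted p = 0.00142, and adjusted p = 0.798 with an estimated correlation), and so was cholesterol synthesis (median 0.30, adjusted p = 0.0347, and adjusted p = 0.855 with an estimated correlation). The cardiac list was lower (median -0.52, adjusted p = 0.00265, and adjusted p = 0.831 with an estimated correlation), and so was the Notch list (median -0.40, adjusted p = 0.0348, and adjusted p = 0.798 with an estimated correlation). Over each of these 4 lists alone 0 members passed. Without PD replicate 2 these did not pass (adjusted p = 0.330, 0.771, 0.771 and 0.244 in that order), and without YZ9 replicate 1 the cholesterol, cardiac and Notch lists did not (adjusted p = 0.519, 0.0924 and 0.251). In the male libraries alone none of the 4 passed (adjusted p = 0.0861, 0.123, 0.111 and 0.0861), and with camera on ranks the Notch list did not (adjusted p = 0.0886). In this comparison edgeR called 12 genes higher and 7 lower, with 1788 at an unadjusted p under 0.05, and DESeq2 called 529 on the filtered genes and 508 without the filter. With the 4 libraries of these groups fitted alone edgeR called 0 (1539 at an unadjusted p under 0.05). Without control replicate 1 or control replicate 2 edgeR called 0 genes (1602 and 1604 at an unadjusted p under 0.05), without PD replicate 1 it called 35, without PD replicate 2 15, without YZ9 replicate 1 13 and without YZ9 replicate 2 7. Across the 93 list tests of the 3 comparisons 30 passed with the preset correlation, and camera with an estimated correlation passed 0, with 9 at an unadjusted p under 0.05, and fry 0, with 16.

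The fold changes of the inhibitors against control were compared across genes, which are not independent replicates. Pearson's r was 0.554 over 15568 genes, against a mean of 0.500 and a highest value of 0.522 in 40 simulations of unchanged groups that shared the control libraries. The covariance was 0.378, against a mean of 0.157 and a highest value of 0.167. The share of genes with the same sign in both, 67.0%, lay within the simulated range of 65.9% to 67.4% (mean 66.7%). Tubb1 was lower with both inhibitors, where simulations gave 0.025 such genes on average and up to 1, and independent lists 0.000771. In edgeR 0 genes were higher with both. At an unadjusted p under 0.05, 258 genes were higher with both (simulated mean 109 and highest 135, independent lists 36.6) and 311 were lower with both (simulated mean 64.5 and highest 78, independent lists 58.1). The covariance was 0.578 without control replicate 1.

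The remaining lists did not pass with PD or with YZ9. Among metabolic and stress lists, the camera adjusted p was 0.374 with PD and 0.772 with YZ9 for the hexosamine pathway, 0.947 and 0.648 for the pentose phosphate pathway, 0.772 and 0.630 for the citric acid cycle, and 0.521 and 0.106 for nuclear genes of oxidative phosphorylation. It was 0.198 and 0.875 for hypoxia genes, 0.634 and 0.187 for targets of ATF4, and 0.772 and 0.165 for cell cycle genes. Among developmental lists it was 0.439 and 0.537 for paraxial mesoderm, 0.174 and 0.634 for lateral and extraembryonic mesoderm, 0.784 and 0.232 for migration and epithelial to mesenchymal transition, 0.165 and 0.609 for the FGF family, and 0.165 and 0.772 for BMP and TGF-beta targets. Markers of tissues next to the mesoderm gave 0.198 and 0.768 for visceral endoderm and 0.772 and 0.280 for trophoblast. Flrt3, a membrane protein of the FGF list, was at 147 ± 33.7 CPM in controls and 711 ± 148 CPM with PD (n = 2, log2 fold change 2.27, SE 0.46, adjusted p = 0.157). The migration list holds both epithelial and mesenchymal genes, and opposite changes of these can cancel in its test. Adjusted over the list alone, 5 members rose and 3 fell with PD, and 4 rose and 8 fell with YZ9. The 4 that rose with YZ9 were the epithelial genes Cdh1, Cldn7, Epcam and Cldn6. Col3a1, a collagen gene of that list, was at 276 ± 25.8 CPM in controls and 41.6 ± 26.9 CPM with YZ9 (log2 fold change -2.73, SE 0.47, adjusted p = 0.172). Zeb2, a transcription factor of the same list, had a log2 fold change of -0.99 with YZ9 (SE 0.17, adjusted p = 0.172). The median, the mean and the test differed in sign for the cell cycle, epiblast, ATF4, ectoderm, paraxial and pentose phosphate lists with PD, and for the migration, FGF, immediate early, lateral mesoderm and Notch lists with YZ9. They also differed in sign for the definitive endoderm, glycolysis, p53 and paraxial lists in PD against YZ9, where none of these passed.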

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

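The newer quasi-likelihood fit, DESeq2 on the filtered genes, the sex covariate and the male libraries alone were chosen only after the results were seen; the other alternatives were planned. For PD against control the main count of 15 genes became 712 without a filter, 604 with DESeq2 run without the filter, 629 with DESeq2 on the filtered genes, 124 with the sex covariate and 428 in the male libraries alone, all 15 among each of these, and 1 with the replicate number as a block. For YZ9 against control the count of 1 became 556 without a filter, 509 and 519 with DESeq2 without and with the filter, 5 in the 4 libraries alone, 122 with the sex covariate, 183 in the male libraries alone and 3 with the block. For PD against YZ9 the count of 19 became 601 without a filter, 508 and 529 with DESeq2 without and with the filter, 34 with limma-trend, 0 in the 4 libraries alone (1539 at an unadjusted p under 0.05), 29 with the newer fit, 173 with the sex covariate, 132 in the male libraries and 12 with the block. Leaving out 1 library gave 0 to 33, 0 to 9 and 0 to 35 genes, and a group left with 1 library is assumed to vary like the others. The spread in the male libraries alone came from the 2 controls. The deviations of the replicates from their group means correlated at -0.10 between control and PD and at 0.15 between control and YZ9. Between PD and YZ9 they correlated at 0.35, and in these groups the replicate number coincides with sex. The count of 30 lists became 0 with an estimated correlation, 0 with fry (9 and 16 at an unadjusted p under 0.05) and 19 in the male libraries, and 22 to 33 without 1 library; the block ended the epiblast call with YZ9 (adjusted p = 0.0636). The covariance of the fold changes was 0.378 in the data, 0.157 in simulated unchanged groups, 0.435 in the male libraries and 0.363 to 0.578 without 1 library. The cause of these changes was not tested, although on filtered genes of simulated data DESeq2 also made more false calls than edgeR (43 against 7).

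Across named genes, 1438 of 1834 comparisons with an alternative kept their direction and side of the threshold, 185 newly passed, 199 no longer passed and 12 turned. Across lists, 232 of 360 kept and 128 no longer passed. The 1834 comparisons cover 108 gene results. Only those past the threshold in the main fit could stop passing: 15 with PD, 1 with YZ9 and 19 in PD against YZ9. The 199 are thus a larger share of the comparisons that could lose a call than of the 1834. The log2 fold change of Ldha with PD, 0.12, was -0.28 with the sex covariate and -0.56 in the male libraries, and ranged from -0.56 to 0.57 without 1 library. That of Dusp6 with YZ9, -0.48, was 0.14 and 0.0188, and ranged from -1.21 to 0.0186. Without 1 library Pfkfb3 ranged from -1.08 to 0.0142 with PD and from -0.79 to 0.87 with YZ9, and with YZ9 Etv4 ranged from -0.64 to 1.26 and Etv5 from -0.23 to 1.47. The cause was not tested. DESeq2 size factors and the stricter filter left PD at 15 and YZ9 at 1 gene. No scaling moved the median of all genes by more than 0.1 on the log2 scale. With 2 libraries a group, simulated 2-fold changes were mostly missed (4.48% recovered by edgeR), so genes not called are not shown to be unchanged.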

Other observations

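The epithelial, platelet-lineage and red-cell lists, the genes summed for visceral endoderm and ectoderm, the fit with sex in the model, the tests of carried-over tissue, blood cells and sex as explanations and the weighing of the shared controls were chosen only after the results were seen, while the edgeR and DESeq2 calls without sex in the model and the correlation and covariance beside simulated groups were chosen before. A list of 20 epithelial genes, 6 of them also in the lists fixed earlier, stood above both controls in both PD libraries for 19 genes and in both YZ9 libraries for 18, which is no test, since the genes were picked after their values were seen. edgeR called 0 of them with either inhibitor, with 18 at an unadjusted p under 0.05 for each, and with sex in the model it called 12 with PD and 10 with YZ9, while DESeq2 without the filter called 13 with PD and 11 with YZ9, and 11 and 14 passed in the authors' deposited table. Cldn6 had 7 and 220 counts in controls, 11667 and 1404 with PD and 4460 and 2239 with YZ9. Epcam had 23 and 67, 1351 and 229, and 857 and 521.

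A list of 14 genes of megakaryocytes and platelets, 1 of them also in the fixed lists, lay below both controls in both YZ9 libraries for 14 genes and in both PD libraries for 10, which is no test either. edgeR called Tubb1 alone among them with either inhibitor, with 13 at an unadjusted p under 0.05 with YZ9 and 7 with PD. With sex in the model it called 6 with YZ9 and 1 with PD. DESeq2 without the filter called 9 with YZ9 and 1 with PD, and 11 and 2 passed in the authors' deposited table. Gp5, a platelet glycoprotein gene, had 132 and 126 counts in controls, 40 and 4 with PD and 0 and 0 with YZ9. Of 12 red-cell genes, 8 of them also in the fixed lists, 10 lay below both controls in both YZ9 libraries and 0 did with PD; edgeR called 0 with either inhibitor (1 at an unadjusted p under 0.05 with YZ9 and 0 with PD), 8 with YZ9 and 2 with PD with sex in the model, and DESeq2 without the filter 1 and 0. Hbb-bh1, an embryonic globin, had 17699 and 42711 counts in controls, 4978 and 86348 with PD and 319 and 13183 with YZ9.

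The values of most of the 20 epithelial genes were higher with both inhibitors, although edgeR called 0 of them without sex in the model (12 with PD and 10 with YZ9 with it). Visceral endoderm left on the explants is argued against for YZ9. There 8 abundant genes of that layer changed by -1.74 CPM in sum (spread 3.16) while Epcam alone gained 26.3 CPM (spread 14.8). With PD, 8 epiblast and ectoderm genes changed by -8.48 CPM in sum (spread 8.86), or by -22.3 CPM (spread 5.04) with Dnmt3b, left out for its 69.4 CPM in controls. Epcam gained 28.9 CPM with PD, but the spread of 30.2 between libraries exceeds that gain. Epiblast or neural ectoderm therefore stays open for PD. Sex alone would leave the male treated libraries near the male controls. Their median log2 fold change over these controls was 3.13 with YZ9 (median absolute deviation over genes 1.68) and 3.66 with PD. The genes were picked after their values were seen in these same libraries, so this is no independent test of sex. For PD, visceral endoderm cannot be told apart from a change within the mesoderm, because its genes gained 45.7 CPM with a spread of 50.8 between libraries. For YZ9, epiblast or neural ectoderm cannot be told apart from such a change either. There the 8 epiblast and ectoderm genes changed by -5.32 CPM (spread 11.2, or -1.84 with a spread of 21.2 with Dnmt3b). The epiblast and ectoderm lists passed upward with YZ9 (camera adjusted p = 0.0465 and 0.0450, and adjusted p = 0.655 for each with an estimated correlation). Both calls ended with camera on ranks and with sex in the model, so they carry little weight. Surface ectoderm stays open: 8 of its genes gained 16.0 CPM in sum with YZ9 (spread 5.61) and 41.8 CPM with PD. These sums rest largely on single genes. Grhl3 went from 4.77 to 47.9 CPM with PD, and Wnt6 from 0.263 to 13.6 CPM with YZ9. A change within the mesoderm stays open too, as does definitive endoderm. The definitive endoderm list shares 4 genes with the 20 and lost its camera calls with an estimated correlation (adjusted p = 0.748 with PD and 0.619 with YZ9).

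The values of the 14 platelet-lineage genes were lower with YZ9, although edgeR called Tubb1 alone without sex in the model (6 genes with it). With sex in the model their median fitted log2 fold change was -4.63 (spread 2.69), a fitted value that includes genes at 0 counts. These genes too were picked after their values were seen in these same libraries, so this is no independent test of sex. Fewer blood cells of every kind stays open. With 0.5 CPM added before the logarithm, the platelet-lineage median minus the red-cell median was -1.26 in YZ9 replicate 2 (spread 1.69) and 2.33 in YZ9 replicate 1 (spread 2.56). Neither library set the lineages apart by more than the spread, but the added 0.5 CPM limits the fall of genes with low CPM. In the main edgeR fit the median log2 fold change with YZ9 was -3.85 for platelet-lineage and -2.26 for red-cell genes. Whether blood precursors were fewer at dissection or were lost in culture stays open.

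Fold changes of PD and YZ9 went together across genes. Sex as the whole cause is argued against, since on the same genes the covariance was 0.408 among the 4 male libraries and 0.378 in all 6. The male treated libraries are both replicate 1, and anything these shared by replicate adds to the 0.408, which weakens the argument. The shared control libraries cannot be told apart from a response common to both inhibitors: the covariance of 0.378, the correlation of 0.554 and the 258 genes higher and 311 lower in both at an unadjusted p under 0.05 lie above the highest simulated values of 0.167, 0.522, 135 and 78, but the share of genes with the same sign, 67.0%, lies within the simulated 65.9% to 67.4%. The simulated values already hold the shared controls at the fitted spread, so part of the excess may come from them only where these controls, too few to split, vary more than that. A difference of the control explants in tissue content or handling stays open too.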
